A study of Hordeum vulgare with 18 samples.

How the data were processed

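The series measured gene expression in immature shoot apices, the growing tips that form the spike, of barley (Hordeum vulgare). Its 18 one-dye (Cy3) microarrays compared BW-NIL(vrs2.e), a line near-isogenic to cultivar Bowman that carries the vrs2.e mutation and is called the mutant here, with Bowman itself, the wild type (WT). Apices were taken at 4 stages: triple mound (TM), glume primordium (GP), stamen primordium (SP) and awn primordium (AP). Groups and replicate numbers came from the sample titles. They give 3, 2, 2 and 2 mutant arrays and 1, 2, 3 and 3 WT arrays at TM, GP, SP and AP. Per the labels' protocols, plants germinated for 14 days under 16 h of light and 8 h of dark, were vernalized for 4 weeks at 4 °C and were hardened for 2 weeks. Also per the labels, total RNA was labelled with the Low Input Quick Amp kit, and 600 ng of cRNA went onto each array of a custom 60k barley design.

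Each array's scanner output holds spot intensity values that the authors obtained with Agilent Feature Extraction 10.7.3.1, per the file headers: background-subtracted and detrended, with low values replaced by small positive surrogates, and not scaled between arrays. The same deposited files carry flags for spots well above background, saturated spots and outlier spots, set by the same software per the file headers. An array has 62976 spots, of which 1818 are controls. The other 61158 spots hold 55835 probes: 50632 on 1 spot, 5188 on 2 and 15 on 10. The authors' deposited table of processed values holds log2-like values for 56375 probes, 55835 of them non-control probes. How it was normalized is not given in the sources used here. Its values follow the scanner values after each probe is centred over the arrays, with a Pearson correlation across probes of 0.708 to 0.983 per array, so its direction is that of the scanner values. Its exact scale and centring stay unknown. Column medians of that table were 0.015, 0.013 and 0 for mutant TM, -0.0076 and -0.00032 for mutant GP, -0.021 and -0.013 for mutant SP, and -0.00083 and -0.00024 for mutant AP. They were 0 for WT TM and both WT GP arrays, 0.0078, 0.012 and 0 for WT SP, and 0.0075, 0.0024 and -0.014 for WT AP. It was used only as an alternative.

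The values analysed were log2(gProcessedSignal) minus the array's 75th percentile of it, after leaving out control spots and 175 outlier spots and averaging the spots of a probe. Probes well above background on at least 2 of the 18 arrays were kept (41136), and 2 without a value in some group were dropped, which left 41134. No spot was saturated (0 on every array). A linear model with 8 genotype-by-stage groups was fitted to all 18 arrays with limma 3.58.1 (lmFit and eBayes; R 4.3.3, statmod 1.5.0, data.table version 1.17.8), so that all groups share 1 estimate of the spread on 10 residual degrees of freedom. The lone WT TM array is thereby assumed to vary like the other groups. A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05. Genotype effects are mutant minus WT, at each stage and as the equally weighted mean of the 4 stages. The interaction is a moderated F test that the 4 effects are equal. Stage steps are the mean of the mutant and WT differences between consecutive stages.

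Where a probe was not well above background on any array of a group, its fold is a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own value. Counts of changes above 2-fold and 16-fold, and median differences, were likewise taken with values not well above background raised to that level.

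The probes carry custom design identifiers, and the files do not pair them with genes. None of them (0) matched an identifier among the 58438 genes of the reference gene table (MorexV3). The 29 gene lists fixed for hormone, meristem, floral and marker genes, their set tests, and a test of location on the chromosome that carries VRS2 were therefore not run, and the expression of VRS2 itself was not checked. The rule for naming probes, fixed before the data were examined, was then limited to the 2 probes with the highest and the 2 with the lowest fitted difference over the mean of the 4 stages among those past the threshold. Their dim side is not well above background, so this choice gives no order of size.

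The 18 arrays lie on 4 slides scanned on 2 days. Slide 1 holds mutant SP replicate 1 and both mutant AP arrays. Slide 2 holds the mutant TM and GP arrays and mutant SP replicate 2. Slide 3 holds the WT TM and GP arrays and WT SP replicates 1 and 2. Slide 4 holds WT SP replicate 3 and the WT AP arrays. All mutant slides were scanned on 1 day and all WT slides on the other, so scan day and genotype cannot be told apart. Slide was used as a random block (duplicateCorrelation; within-slide correlation 0.496) and, for stage steps and the interaction, as a fixed block. The labels do not say that replicates are separate plants or pools, so p-values measure only the spread between these arrays, which may be technical.

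Duplicate spots separated array differences from spot noise on 3860 probes. In the 4 replicate pairs of mutant TM and GP, the SD beyond spot noise was 0.0425 to 0.0606 log2, below a spot noise of 0.0975 to 0.142. In the 9 other replicate pairs it was 0.143 to 0.618, against 0.0690 to 0.126. The differences of duplicate spots still correlated in the former (Pearson r across probes 0.138 to 0.277), so these arrays are not copies of 1 scan. They stayed separate, as the design was fixed, and the main counts of genotype effects, the interaction and the stage steps are also given with the mutant TM and GP arrays averaged to 1 array per stage.

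Other settings tried, fixed at the same time, were quantile scaling, other filters on dim probes (none, or 9 arrays), the deposited value table, slide blocks, the replicate number as a block, array weights, a trended robust prior, only the 2 groups compared, an additive model, fewer stages, and leaving out each array. Normexp on the mean signal was planned, but the files hold no such column, so it was run on the median signal and median background (offset 50). That version, the averaging of arrays, the restriction to SP and AP the steps within 1 genotype with their own alternatives, and the sizes with dim values at their bound were chosen after seeing the data. The median log2 effect over all probes shifted with the scaling. It was 0.15 at TM, 0.08 at GP, -0.01 at SP and -0.04 at AP, against 0.39, 0.29, -0.18 and -0.31 under normexp and 0.07, 0.04, -0.02 and 0.01 under quantile scaling.

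The fit was tested on simulated values of the 41134 probes, with 50 probes changed at each fold and all others unchanged. The simulated noise was independent and normal, with 1 SD per probe for all groups. Correlation within slides and unequal spread between groups were not simulated, so the shares and false calls hold for that simpler setting only. For the mean of 4 stages it recovered 62% of 1.5-fold, 78% of 2-fold, 94% of 4-fold and 100% of 8-fold changes, with 7 false calls. At TM the shares were 20%, 44%, 76% and 88%, at GP 26%, 42%, 78% and 88%, at SP 32%, 60%, 80% and 94%, and at AP 32%, 54%, 78% and 92%. For the WT step from SP to AP they were 36%, 60%, 80% and 96%. For the interaction they were 12%, 28%, 76% and 80%, with the change placed on the mutant TM and GP arrays only. Other patterns of interaction were not simulated. Array signal at the 75th percentile ranged from 430 (WT SP replicate 2) to 1335 (mutant AP replicate 2), and the share of probes well above background from 59.9% (WT SP replicate 2) to 70.1% (WT AP replicate 3). The number of arrays limits the precision.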

Results

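Shoot apices of the barley vrs2.e mutant and of its Bowman parent were profiled while the spike formed its spikelet, glume, stamen and awn primordia, with 9 arrays per genotype over 4 stages. VRS2 encodes a transcriptional regulator of the SHORT INTERNODES family that controls the row type of the barley spike. The series title names hormone-mediated patterning of the inflorescence as the subject. Probes are reported by identifier because the files pair none of them with a gene.

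The early mutant arrays stood apart from all other groups. The 5 mutant arrays of the TM and GP stages resembled one another (Pearson r across probes 0.978 to 0.994) and differed from the 12 arrays that remain after mutant SP replicate 1 is set aside (r 0.837 to 0.870). Those 12 arrays, the 9 WT arrays of all 4 stages and 3 late mutant arrays, correlated at 0.960 to 0.992 among themselves. Mutant SP replicate 1 lay between, at 0.910 to 0.920 with the early mutant arrays and 0.940 to 0.963 with the 12. The first principal component held 72.1% of the variance and the second 7.84%. These correlations are across probes, which are not independent replicates. Spike-in controls stood higher, relative to the 75th percentile, on the mutant TM and GP arrays, with no test made (mean log2 0.93 and 1.04, n = 3 and 2) than on the mutant SP and AP arrays (0.31 and 0.25, n = 2 each). WT groups averaged 0.08 (TM, n = 1), 0.83 (GP, n = 2), 0.79 (SP, n = 3) and 0.68 (AP, n = 3), and single WT SP arrays ranged from -0.34 to 2.28.

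**Figure D1:**
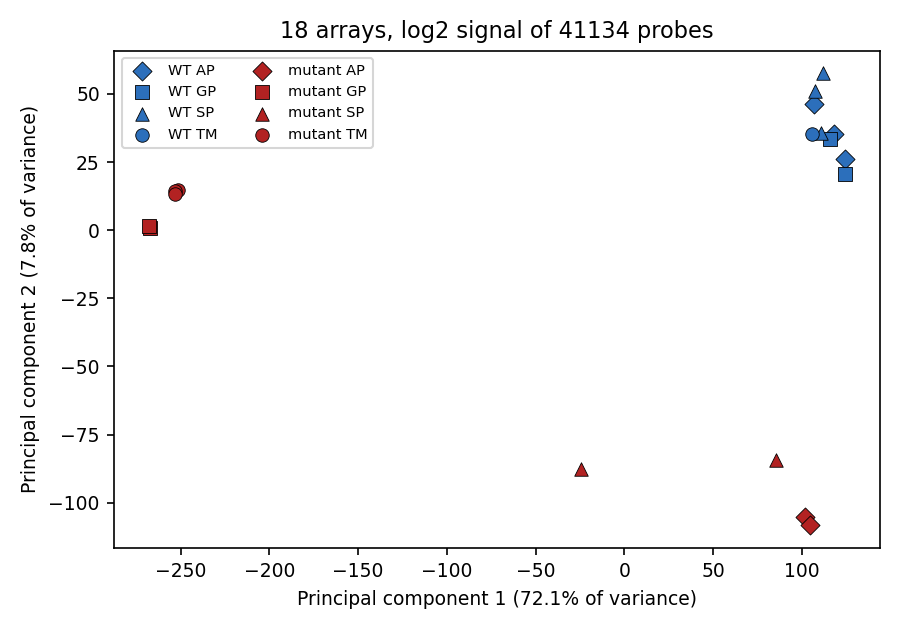
Principal components of the 18 arrays from the log2 signal of 41134 probes, with 72.1% of the variance on the horizontal and 7.84% on the vertical axis; each point is 1 array, coloured by genotype and shaped by stage. The 5 mutant TM and GP arrays stand apart from the WT arrays, with mutant SP replicate 1 between them.

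The first comparison asked which transcripts differ between mutant and WT across the 4 stages. A small number of probes were bright in one genotype and not well above background in the other at every stage. CUST_100479_PI403524517 was well above background on 9 of 9 mutant and 0 of 9 WT arrays, and was at least 779-fold higher in the mutant (limma with Benjamini-Hochberg adjusted p = 1.66e-11). CUST_15772_PI404877155 showed the same pattern and was at least 786-fold higher (limma adjusted p = 1.07e-13). CUST_103952_PI403524517 was well above background on 9 of 9 WT and 0 of 9 mutant arrays and was at least 582-fold lower in the mutant (limma adjusted p = 5.48e-15). CUST_23381_PI399408534 was at least 224-fold lower (limma adjusted p = 3.80e-15). The p-values rest in part on the spread of values that are not well above background, and the folds hold for the scaling used. In the order named, the fitted log2 differences were 10.60, 10.38, -9.78 and -8.96, and 6.05, 5.68, -5.31 and -4.24 under normexp, which adds an offset of 50. In all, 66 probes were detected on all 9 mutant and no WT array, by a median of at least 4.73-fold, and 11 on all 9 WT and no mutant array, by a median of at least 24.8-fold.

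**Figure D2:**
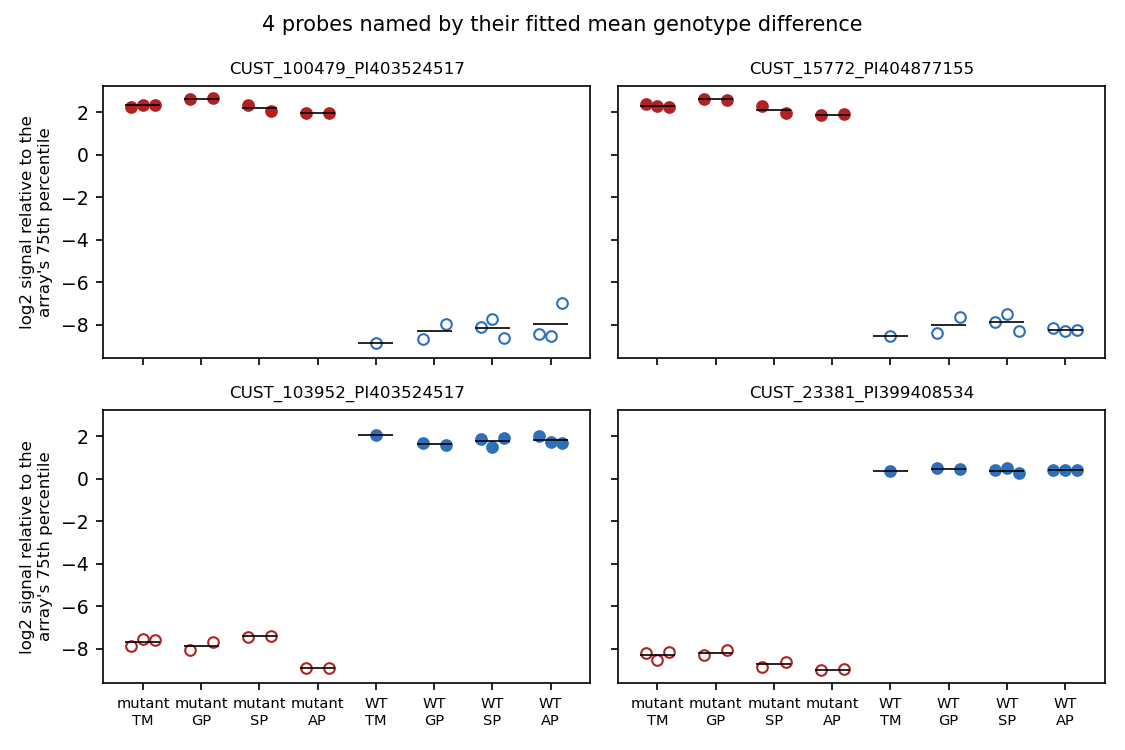
Log2 signal relative to the array's 75th percentile for the 4 probes named by their fitted mean genotype difference, by genotype and stage; each point is 1 array, filled where well above background and open where not, and lines are group means. The pairs of probes that rose and fell keep their state in all 18 arrays.

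Over the mean of the 4 stages, 30515 of 41134 probes (74.2%) differed between genotypes, 15749 higher and 14766 lower in the mutant, and 9583 of them by more than 2-fold with dim values at their bound. The mean over stages combines early effects that are far larger than the late ones. With SP and AP alone it gave 19591 probes, and 18947 when mutant SP replicate 1 was also left out. With slide as a random block, 22238 probes were called, and with the close mutant TM and GP replicates averaged, 27776. Scan day followed genotype exactly, so none of these counts separates them.

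At TM, 26711 probes (64.9%) differed, 14077 higher and 12634 lower in the mutant. With dim values at their bound, 8414 rose and 7973 fell by more than 2-fold, and 1630 probes changed more than 16-fold. At GP, 29078 probes (70.7%) differed, 14996 higher and 14082 lower, with 9241 up and 9040 down by more than 2-fold and 1944 by more than 16-fold. The median absolute difference was 0.83 log2 at TM and 0.93 at GP. The profiles of both stages were similar but not identical: the effects correlated at r = 0.914 across probes, and of 23937 probes called at both, 99% went the same way (12311 up and 11389 down at both, against 5132 and 4325 for independent lists) and 237 opposite ways. The TM and GP arrays of each genotype share a slide. All stage effects share each probe's estimate of the spread, and scan day follows genotype, so independent lists are a low baseline for every such overlap. Detection set the early mutant arrays apart as well: 161 probes were well above background on all 5 mutant TM and GP arrays and on none of the other 13, and 535 the reverse, by medians of at least 9.52-fold and 9.77-fold. The other 13 include mutant SP replicate 2, which lies on the same slide. By the same rule the 3 WT TM and GP arrays set apart 2 and 6 probes. WT had 1 array at TM. The mutant replicates of both stages differed by less than spot noise, and with each stage's mutant arrays averaged to 1 the counts were 21749 at TM and 25197 at GP, and, as all groups share the spread, 12785 at SP and 9537 at AP.

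The difference between mutant and WT was smaller at the later stages. At SP, 16076 probes (39.1%) differed, 7791 higher and 8285 lower in the mutant, with 2131 up and 1662 down by more than 2-fold. At AP, 12827 probes (31.2%) differed, 6106 higher and 6721 lower, with 1465 up and 1505 down by more than 2-fold. The median absolute difference was 0.36 log2 at SP and 0.31 at AP. The effects at SP and AP correlated at r = 0.643 across probes, and of 9171 probes called at both, 4427 rose and 4698 fell at both stages, against 1157 and 1354 for independent lists, while 46 went opposite ways. The groups share no array, but slides 1 and 4 hold arrays of both stages. Both effects also use the same estimate of each probe's spread, and scan day follows genotype at both stages. Independent lists are thus a low baseline, and the excess alone does not show a repeated effect of the mutation. At SP, only 474 probes were called when the 2 SP groups were fitted alone and 5619 with array weights, and the 2 mutant SP arrays differed with an SD beyond spot noise of 0.618 log2, the highest of all replicate pairs. At AP, the count was 23938 under normexp, 6147 with slide as a random block and 19874 with array weights, and it was 7446 without mutant AP replicate 1 and 8235 without mutant AP replicate 2. The share of called probes that were higher in the mutant was 48.5% at SP and 47.6% at AP, but 39.2% and 21.7% under normexp.

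**Figure D3:**
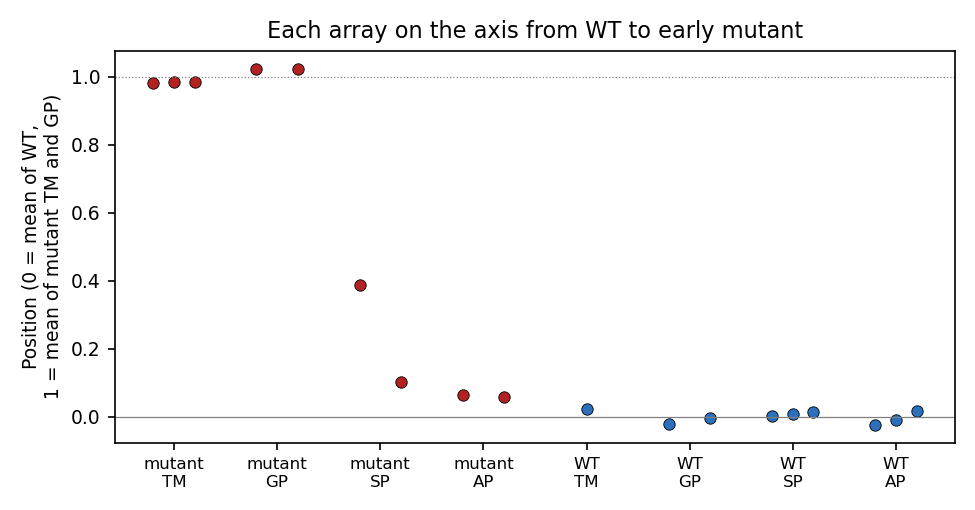
Position of each array on the axis from the mean WT profile (0) to the mean mutant TM and GP profile (1); each point is 1 array, grouped by genotype and stage. Mutant SP replicate 1 lies at 0.387 and SP replicate 2 at 0.103, the mutant AP arrays at 0.0647 and 0.0587, and the WT arrays between -0.0247 and 0.0217.

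The difference between mutant and WT arrays varied with stage. The limma interaction test called 26506 probes (64.4%), and 24607 (59.8%) when only GP, SP and AP were compared. With the mutant TM and GP arrays averaged it called 20719. Between SP and AP alone it called 19 probes, and 119 when mutant SP replicate 1 was left out. The TM effect correlated with the SP effect at r = 0.466 and with the AP effect at r = 0.114 across probes. Of 9643 probes called at both TM and AP, 66.3% went the same way, with 3028 up and 3367 down at both against 2090 and 2064 for independent lists. GP behaved likewise, at r = 0.477 with SP and 0.109 with AP. At all 4 stages 6666 probes were called, of which 2494 rose at each stage, 2858 fell at each and 1314 changed direction. Of 30152 probes well above background on all 18 arrays, the interaction called 22053 (73.1%). The 4 probes named above were not well above background in one genotype at any stage, so how their effect varied with stage is not given.

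The last comparison followed each genotype from stage to stage. From GP to SP the mutant changed at 26083 probes, 12382 up and 13701 down, with 13899 by more than 2-fold with dim values at their bound, and WT at 1700, 692 up and 1008 down. The step itself differed between genotypes at 22813 probes (limma, test of the difference). Across probes the mutant and WT steps correlated at r = -0.116, and of 1374 probes called in both, 490 moved the same way. The mean of both genotypes gave 21677 probes, and 17177 with the mutant TM and GP arrays averaged. The WT count was 488 without WT GP replicate 2, 821 without WT GP replicate 1 and 3783 without either mutant SP array, which share the estimate of the spread. It was 839 in a fit of the 9 WT arrays alone and 582 with the mutant TM and GP arrays averaged, while the mutant count was then 21111. With slide as a fixed block the WT count was 3654.

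From TM to GP, 3371 probes changed in the mean of both genotypes, 1879 up and 1492 down, with 10295 in the mutant alone and 60 in WT alone. The WT count was 256 without either mutant SP array, 254 without WT GP replicate 1 and 110 without WT AP replicate 3. It was 170 with slide as a random block, 392 with slide as a fixed block and 22 in a fit of the 9 WT arrays alone. The step differed between genotypes at 4304 probes (limma). These counts rest on the close mutant replicates: averaged to 1 array per stage they gave 299 for the mean, 1086 for the mutant and 35 for WT. The share of probes that rose was 55.7%, but 35% under quantile scaling, 66.7% under normexp and 36.1% in the deposited table, so no direction is given for the step as a whole. Leaving out arrays moved the mean count between 1651 (without WT GP replicate 2) and 6465 (without either mutant SP array), and the mutant count to 6367 and 5933 without mutant GP replicates 1 and 2.

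From SP to AP, 2066 probes changed in the mean of both genotypes, 1162 up and 904 down, with 3025 in the mutant, 1536 up and 1489 down. In WT, with 3 arrays per stage, 14 probes were called by limma, 13 up and 1 down, and 3340 had an unadjusted p under 0.05. The simulated test, with independent noise of equal spread in all groups, recovered 60% of 2-fold changes for this WT step. The step differed between genotypes at 19 probes. These counts are unstable: with the mutant TM and GP arrays averaged the mutant count was 145, and it was 173 without mutant AP replicate 2, 338 without AP replicate 1, 761 without SP replicate 1 and 14232 without SP replicate 2. Mutant SP replicates 1 and 2 lie on different slides and both mutant AP arrays on slide 1; the mutant count was 11364 with slide as a random block, 14935 with slide as a fixed block and 543 in a fit of the 9 mutant arrays alone. With 1 array left out, the WT count ran from 0 (for example without mutant TM replicate 2, with 2951 at an unadjusted p under 0.05) to 186 (without either mutant SP array). It was 0 with slide as a random block (3399 unadjusted) and 408, 176 up and 232 down, with slide as a fixed block, so no direction is given for this WT step.

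**Figure D4:**
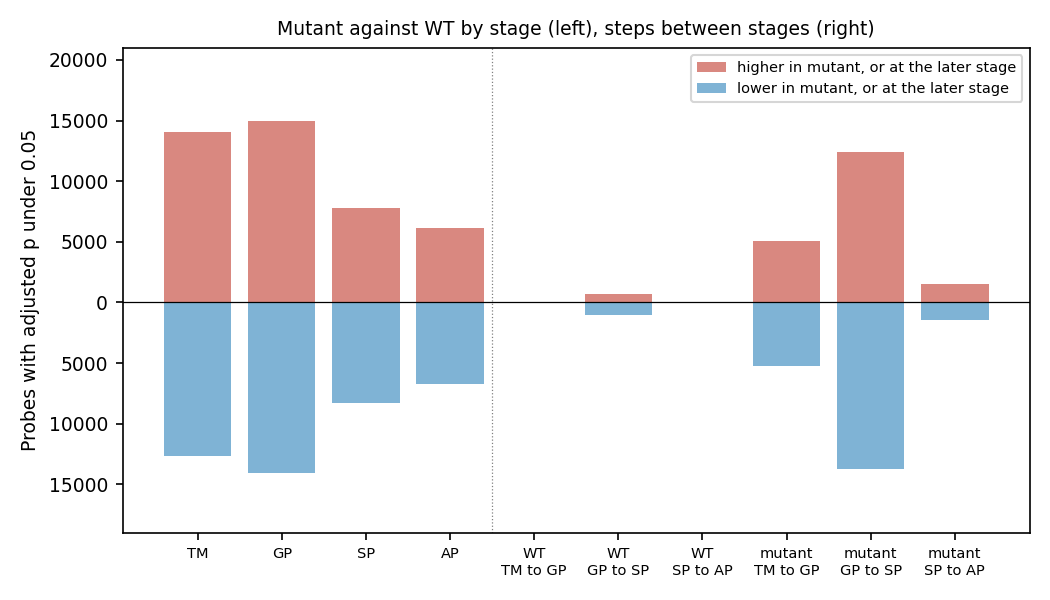
Number of probes past the adjusted p threshold of 0.05, for mutant against WT at each stage (left) and for steps between stages within each genotype (right); bars above 0 are higher in the mutant or at the later stage, bars below 0 lower. The mutant step from GP to SP (26083 probes) approaches the GP genotype difference (29078), and the WT steps stay at 60, 1700 and 14.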

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

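The tests of slide or scan for the early mutant arrays, of the probes gained there, and of a mixture and the slide for mutant SP replicate 1 were chosen after the result was seen. The verdict on exchanged labels uses a bound set after its value was seen.

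The difference between mutant and WT arrays varied between stages at 26506 of 41134 probes, which marked it for a closer look. The pattern behind it is that the 5 mutant TM and GP arrays stand apart. A slide or scan effect is argued against, because mutant SP replicate 2, on the same slide and scanned with them, correlated better with the mutant AP arrays of another slide, by 0.120. Labels exchanged between the genotypes are argued against too, less firmly. Of 63 probes on in one genotype and off in the other at SP and AP, 81.0% kept the mutant state on these arrays. The Wilson 95% interval was 69.6% to 88.8%, and the lowest share of a single array was 76.2%. The bound of 90% set beforehand was not met. The WT TM and GP arrays kept the WT state at 79.4%. The interval treats probes as independent. All were scored on the mean of the same 5 arrays, so it does not measure sampling uncertainty. The verdict rests on the shares lying above 50%, a criterion chosen after the value was seen. For the 161 probes gained, a lower hybridisation yield is argued against only in that it should lose probes and gain hardly any. The same rule gave 2 on the WT TM and GP arrays. Their 75th percentile was 721 to 1102, so that count does not show what a low yield gives. For the 535 probes lost, the test set beforehand could not decide, as probes gained were 30.1% of those lost, between its bounds. Array signals, compared after the result was seen, do not decide it either. The 75th percentile was 494 to 628 on these 5 arrays. It was 430 on WT SP replicate 2 and 533 to 618 on the WT AP arrays. Those WT arrays detected the lost probes by definition, since only probes detected on all 13 other arrays were counted. A 75th percentile this low thus did not by itself prevent detection, but a lower yield stays open for the lost probes. A biological difference of the mutant at early stages, another makeup of the sampled tissue and RNA quality stay open and untested, since no probe has a gene name.

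Mutant SP replicate 1 lies between the early mutant arrays and the rest, at 0.387 of the way. A single mixture of early mutant RNA with SP RNA should give 1 fraction from all probes. On the linear scale, 809 probes high in the early mutant gave a fraction of 0.0983 (95% bootstrap interval 0.0831 to 0.130, quartiles 0.0195 to 0.347). The 923 probes low in the early mutant gave 0.432 (0.423 to 0.440, quartiles 0.352 to 0.506), a gap of 0.333. The estimate assumes that the arrays share 1 linear scale, and a scale offset of SP replicate 1 could also give a gap. The SP reference was 1 array, so a mixture is neither shown nor excluded. A slide effect is not decided either. The slide mates of mutant SP replicate 1, the mutant AP arrays, lay at 0.0647 and 0.0587 and did not share its shift. Relative to mutant SP replicate 2 they lay at -0.0410, that is, no closer to the early mutant arrays. But SP replicate 2 shares the slide of the early mutant arrays, which define the axis, and the mates are of another stage. Apices between the GP and SP stages remain a candidate explanation that was not tested.

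Some probes were on in one genotype and off in the other, which a slide batch could give. At SP, 0 probes differed by more than 6 log2 between the mean of WT SP replicates 1 and 2 and WT SP replicate 3 on another slide. Between the single arrays mutant SP replicate 2 and WT SP replicate 3 there were 58, so the share was 0%. The means of the mutant and WT arrays of SP and AP gave 21. Slide alone is thus argued against only for gaps above 6 log2. The median gap was 2.62 log2 for the 66 probes detected only in the mutant and 5.50 for the 11 detected only in WT. Smaller gaps, as most of these had, were not tested, and scan day cannot be told apart from genotype. Differences in the probe targets between the introgressed donor segment and Bowman, and changes in transcript level, both stay open and untested. The limma interaction test passed its threshold for CUST_103952_PI403524517 and CUST_23381_PI399408534 (adjusted p = 0.000235825 and 0.00756725). Neither is shown to depend on stage: the mutant values, not well above background on any of the 9 arrays, spanned 1.49 and 0.81 log2 between stage means, and the measured WT values 0.45 and 0.12.

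Outside the comparisons above, 499 custom probes that the array design marks as controls were all well above background on at least 2 arrays, 15 of them also present among the probes analysed. With the same limma fit, 461 changed with genotype over the mean of 4 stages, 60 up and 401 down, and 415 had an interaction. Of the main probes called for that mean, 48.4% were lower in the mutant. Why the control-marked probes fell more often was not tested.

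Of 100 splits drawn from 2400 within stages, the real one included, 1 gave as many genotype calls, the real one itself. None of the other drawn splits reached its count. The splits move arrays across slides, whereas each slide holds 1 genotype and the close mutant replicates may be technical (averaged, they gave 27776 calls), so an effect of slide or scan day is not excluded by them. On 41031 probes with a value on every array the real split gave 30453 and the highest other 25367, from 4 relabelled arrays: mutant SP replicate 2 and AP replicate 2 against WT SP replicate 1 and AP replicate 2. That split leaves the early mutant arrays together, a structure of the samples, while 5 of the other splits exceeded 1000 calls and the median of the other splits was 0. The split counts therefore do not exclude chance for the labels of the late arrays. For the WT step from SP to AP, 2 of 10 splits gave as many calls, with 14 for the real one and 18 for the highest other, and 10 splits are too few for a share under 0.05.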

How the results depend on the processing

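Normexp on median signals, the averaged mutant arrays, SP and AP alone and steps within 1 genotype were chosen after seeing the data. Of 111 alternative counts, 84 lay within 1.5 times the count reported, and so did 134 of 158 with 1 array left out. The 84 values computed for the 4 named probes all kept direction and call, with log2 differences of 6.05, 5.68, -5.31 and -4.24 under normexp. These probes were picked as the extremes of the same fit, so their stability is no independent support. None of these settings separates genotype from scan day. The cause of the other shifts was not tested. No alternative moved the TM or GP genotype counts by more than 1.5 times. The mean of 4 stages (30515) was 19591 for SP and AP and 18947 without mutant SP replicate 1 as well. At SP (16076), array weights gave 5619 and the 2 groups alone 474, although the same restriction gave 16087 at AP. At AP (12827), normexp gave 23938, slide as a random block 6147 and array weights 19874. The interaction (26506) was 19 between SP and AP, 119 without mutant SP replicate 1. From GP to SP (21677), WT alone gave 1700.

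From TM to GP (3371), the counts were 1774 with normexp, 2172 without a filter, 5683 and 7442 with slide as a random and a fixed block, 2140 with the replicate block, 9603 with array weights, 60 in WT, 10295 in the mutant and 299 with mutant arrays averaged. From SP to AP (2066), they were 1037 without a filter, 7843 and 12589 with slide random and fixed, 1268 with the replicate block, 328 with array weights, 3205 with a trended robust prior, 14 in WT and 350 with mutant arrays averaged.

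With 1 array left out, the counts ran from 7446 to 16027 at AP, 1651 to 6465 from TM to GP and 439 to 12830 from SP to AP. From TM to GP they were 2178 without mutant TM 1 or 2, 2082 and 1763 without mutant GP 1 and 2, 6465 without either mutant SP array and 2180 and 1651 without WT GP 1 and 2. From SP to AP they were 1338, 1262 and 1285 without mutant TM 1 to 3, 1344 without either mutant GP array, 12830 without mutant SP 2, 617 and 439 without mutant AP 1 and 2, 1338 without either WT GP array, 3261 and 1373 without WT SP 2 and 3, and 760 and 877 without WT AP 1 and 2. Leaving out WT TM gives no value where that group enters.

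Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.0852 at GP, -0.0666 and 0.0116 at SP, and -0.00975 and -0.0394 at AP. With the replicate block the counts were 30130 for the mean, 25693 at TM, 28752 at GP, 14859 at SP, 11255 at AP and 24792 for the interaction. Gene list and location alternatives were not run, as no probe has a gene name. Signals not well above background limit folds to bounds.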

Other observations

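Developmental delay or advance of the mutant was one hypothesis for its early profile, and the test against the WT stages sampled was chosen after the result was seen. The mutant TM profile resembled that of no WT stage sampled. The highest correlation of a mutant TM array with any WT array was 0.868, while WT arrays of all 4 stages correlated at 0.975 to 0.992 with one another and the later mutant arrays (SP replicate 2 and AP) at 0.960 to 0.975 with WT. Tissue makeup, RNA quality or the genotype could lower this correlation at any stage, so it does not place the mutant TM apices in the WT course. A stage within or outside those sampled in WT stays open. If the early mutant profile lay along an extension of the WT course, its difference from WT could follow the WT change from GP to AP. Across 41134 probes that correlation was r = 0.10 (Spearman rho 0.119), just above the bound of 0.1 set beforehand for a negative result and below the 0.3 set for a positive one. Among the 2584 probes called between GP and AP in WT, r was 0.252 and 62.2% moved the same way. The WT TM and GP arrays lie on slide 3 and the WT AP arrays on slide 4. Both differences thus subtract arrays of slide 3, and a slide effect alone could raise either r. That set is unstable: it held 1105 and 904 probes without WT GP replicates 1 and 2, 1607 and 1402 without WT AP replicates 1 and 2, 5000 without either mutant SP array, 1006 with the mutant TM and GP arrays averaged, 1167 with slide as a random block and 1520 in a fit of the 9 WT arrays alone. Both r lie between the bounds, so an extension beyond the sampled stages is neither shown nor excluded.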
